A study of Arabidopsis thaliana with 33 samples.

How the data were processed

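Libraries were made, per the labels, from the aerial parts of 20-day-old Arabidopsis plants of 11 genotypes with 3 libraries each, 33 in all. Per the labels total RNA came from a column kit, poly(A) RNA was prepared with a TruSeq kit whose strandedness they do not state, and paired ends were read on an Illumina HiSeq X instrument. The labels number the 3 libraries of a genotype as replicates without saying whether they were separate sowings. The authors' p-values can therefore reflect at most the spread between these samples. How that spread entered their test cannot be checked without library values.

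Per the submitters' processing notes the authors aligned reads to TAIR10 with TopHat2 2.1.1 and computed values with Cuffdiff, whose version the sources used here do not give. FPKM values in the deposited table are read fragments scaled by transcript length and library size, pooled by the authors over the libraries of a genotype, 1 value per gene and genotype, with no library values, SD or n. The log2 ratios in the deposited table are the authors' ratios of pooled FPKM, given for 8 comparisons. The p-value and q-value (FDR) columns of the deposited table came from the authors' Cuffdiff test and its multiple testing correction. The authors' log2 ratios of the ski2-2 dcl4-2 comparisons with Col-0 and dcl4-2 differ from the ratios of the listed FPKM by constants of 0.0132 and 0.0163, so at least 2 normalization runs stand behind the table.

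The planned test between libraries could not be made, because the table holds group values alone, and the written fallback of giving values without a test was followed. The authors' tests were used for the 8 comparisons and size alone for 9 others and for the interactions. A gene counted as changed at a q of 0.05 and a log2 ratio of 1 in the authors' deposited table with at least 1 FPKM in a compared genotype. Where there was no test, a log2(FPKM + 1) difference of 1 was used. Genes were ranked by the log2(FPKM + 1) difference among those with at least 5 FPKM in a compared genotype, 5 each way for the 4 main comparisons and 3 each way for the others. Genes listed at 0 in either compared genotype were left out of this ranking. A clause of the naming rule that required no overlap between libraries could not be applied. List examples were the 4 largest changes of a list, and further members were named where few passed. Folds against a listed 0 were not computed.

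Gene symbols came from the TAIR10.1 names, which matched 32810 of 33557 identifiers; coordinates were not used. The 20 lists fixed before the data were examined covered the mutated genes, siRNA source genes, RNA silencing, RNA decay, miRNA targets, tasiRNA loci and targets, nitrogen, ABA and drought, salicylic acid, jasmonate, ethylene, photosynthesis, ribosomal proteins, anthocyanin, senescence, cell division, heat shock, clock, floral and root genes. Of 6 added lists, dawn output, evening output and a second root list were written before the values they test were seen, and sulfur, iron and phosphate limitation after. List medians were placed among 10000 random lists drawn from 20 bins of mean expression (seed 1); this is descriptive. Counts adjusted over a list alone are given where they differ.

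Read depth is unknown because the table has no counts, so the precision of a value cannot be stated beyond the authors' test. FPKM sums per genotype were 753957 to 1352350, and the 10 highest genes took 6.14% to 13.9% of the sum. Scripts ran in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9.

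The code was tested on simulated data built from 17988 genes, with 200 changed genes and noise of 0.1 (log2). Changed genes were given a low q by construction, so this checked the arithmetic alone. Calls with q found 100% of genes at 3, 4 and 8-fold and 0% at 1.5-fold, and 0 unchanged genes were called. Calls by size found 94%, 92% and 98% at 3, 4 and 8-fold. A planted list of 20 genes shifted by 1 had a median of 1.01, and 11 of 100 unplanted lists lay outside percentiles 5 to 95. Alternatives tried were a pseudocount of 0.1, an FPKM minimum of 5 or none, the log2(FPKM + 1) difference in place of the authors' ratio, no minimum log2, quantile normalization, median-of-ratios scaling, leaving out genes that differed in dcl2-1 or ein5-1, and controls that share no library. In tested comparisons the pseudocount and scaling alternatives replaced the log2 ratio alone and kept the authors' q. Genes that did not pass that q could not enter.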

Results

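Poly(A) RNA of the aerial parts of Arabidopsis plants was sequenced in 33 libraries of 11 genotypes, with 3 libraries per genotype. Plants were 20 days old, after 6 days on MS medium and 14 days in soil, and all genotypes were labelled as collected at 15:00. The genotypes were the wild type Col-0, the single mutants ein5-1, ski2-2, dcl4-2 and dcl2-1, and 6 double and triple mutants. EIN5 is a cytoplasmic exoribonuclease, and SKI2 is a helicase that feeds RNA to the exosome. DCL4 and DCL2 are Dicer-like enzymes that cut double-stranded RNA into siRNAs of different lengths. The series asked, by its title, about siRNAs of the kind that DCL2 makes, translational repression and stress adaptation.

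The table held 1 pooled FPKM per gene and genotype, so no value below has an SD or an n. It listed 33557 genes, of which 20704 reached 1 FPKM in at least 1 genotype and 7038 were at 0 in all. FPKM sums ran from 753957 in ski2-2 dcl4-2 to 1352350 in ein5-1 dcl2-1, and read depth was not given. Between 17958 and 18976 genes reached 1 FPKM per genotype. For 8 comparisons the authors' deposited table also gave a log2 ratio, p and q, and a gene is said to have risen or fallen only if it passed that q at 0.05, changed at least 2-fold and reached 1 FPKM. The smallest q in the authors' deposited table was 0.000201 for the ein5-1 comparisons and 0.000211 for the ski2-2 comparisons, shared by many genes, and it does not rank them. Other comparisons had no test, and their genes are given by size alone. Statements of the largest changes leave out genes listed at 0 in either compared genotype. Gene lists were fixed before the data were examined unless said otherwise, and a list's median is given on the log2(FPKM + 1) scale.

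The mutated genes were read first. EIN5 (AT1G54490) was at 6.88 to 11.2 FPKM in the 4 genotypes with ein5-1 and at 13.4 to 20.8 FPKM in the 7 without it. DCL2 (AT3G03300) was at 1.23 to 2.35 FPKM in the 5 genotypes with dcl2-1 and at 4.89 to 9.02 FPKM in the other 6. SKI2 (AT3G46960) overlapped, at 2.62 to 3.90 FPKM with ski2-2 and 2.82 to 6.91 FPKM without. DCL4 (AT5G20320) also overlapped, at 2.98 to 4.89 FPKM with dcl4-2 and 3.15 to 6.91 FPKM without, so the transcript level of these genes does not separate the genotypes. Of the targets of trans-acting siRNAs (tasiRNAs), which DCL4 makes, ARF4, HTT1 and HTT2 did separate dcl4-2. ARF4, an auxin response factor, was at 30.5 to 60.2 FPKM with dcl4-2 and at 7.86 to 14.6 FPKM without. HTT2 was at 20.9 to 49.2 FPKM against 8.54 to 15.8 FPKM, and HTT1 at 1.497 to 14.1 FPKM against 0.0742 to 0.742 FPKM. The other targets on the list overlapped: ARF3 at 14.0 to 31.3 FPKM against 6.85 to 15.2 FPKM, PAP1 at 8.98 to 276 FPKM against 5.94 to 103 FPKM, and also ARF2, PAP2, MYB113, AFB2, AFB3 and TIR1. No value contradicted a label at these genes.

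**Figure D1:**
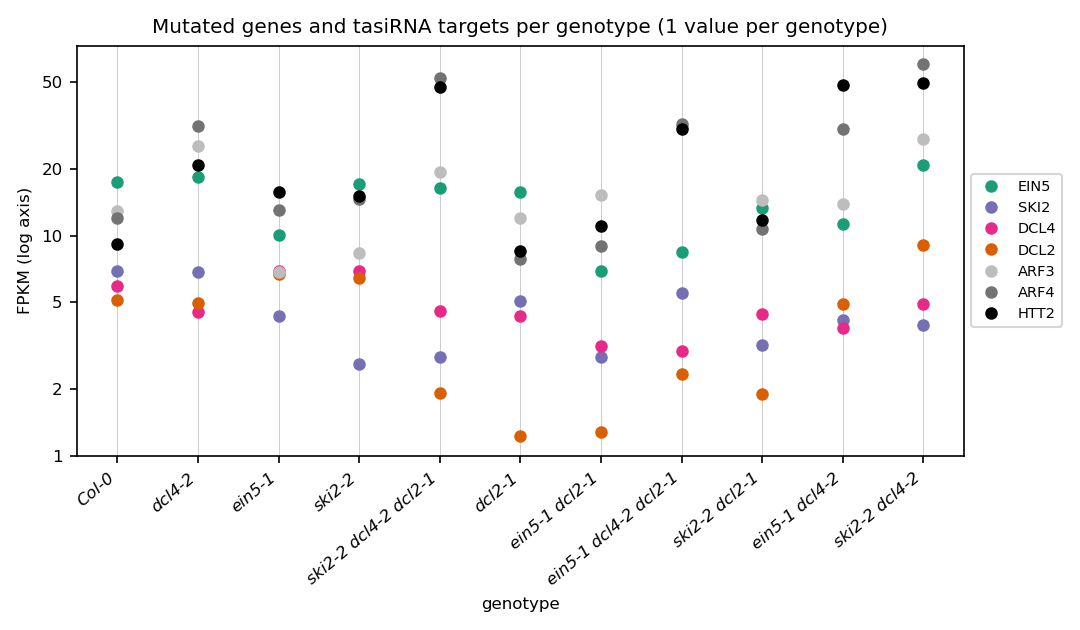
FPKM (log axis, 1 pooled value per genotype, no error) of the 4 mutated genes and of the tasiRNA targets ARF3, ARF4 and HTT2 in the 11 genotypes. DCL2 stayed at or under 2.35 FPKM in the 5 genotypes with dcl2-1, and ARF4 was at or above 30.5 FPKM in the 5 with dcl4-2.

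Genes of the circadian clock differed between genotypes although all carried the same collection hour. The morning gene CCA1 was at 3.32 to 9.34 FPKM in dcl2-1, ski2-2 dcl2-1, the triple ein5-1 dcl4-2 dcl2-1 and ein5-1 dcl2-1. It was at 85.5 to 180 FPKM in Col-0, dcl4-2, ein5-1, ski2-2 and ski2-2 dcl4-2 dcl2-1. LHY was at 1.66 to 3.57 FPKM in the first 4 genotypes and at 47.3 to 232 FPKM in the other 5. PRR5, expressed later in the day, was at 15.1 to 31.1 FPKM in the first 4 and at 0.117 to 0.568 FPKM in the other 5, and ELF4 at 47.8 to 97.7 FPKM against 1.98 to 5.03 FPKM. The doubles ein5-1 dcl4-2 and ski2-2 dcl4-2 had CCA1 at 69.3 and 80.0 FPKM with PRR5 at 11.9 and 12.7 FPKM. Flavonoid genes moved with this split, since CHS (chalcone synthase) was at 47.8 to 113 FPKM in the first 4 genotypes and at 676 to 1556 FPKM in the other 5. Lists of 10 dawn-phased and 7 evening-phased output genes, added before the tested values were seen, had 1 rise and 2 falls and 3 rises and 0 falls in ein5-1 dcl4-2 over Col-0, by the authors' deposited table. In ski2-2 dcl4-2 over Col-0 they had 1 rise and 3 falls and 3 rises and 0 falls. On adding dcl2-1 to ein5-1 dcl4-2 the dawn list had 1 rise and 7 falls and the evening list 1 rise (GRP8, from 308 to 716 FPKM) and 3 falls. On adding it to ski2-2 dcl4-2 the dawn list had 3 rises, CAT2 from 516 to 2170.2 FPKM among them, and 2 falls, and the evening list 0 rises and 5 falls. Comparisons of dcl2-1, ski2-2 dcl2-1, the triple ein5-1 dcl4-2 dcl2-1 or ein5-1 dcl2-1 with the other genotypes therefore also compare different clock states, and the comparisons of ein5-1 dcl4-2 and ski2-2 dcl4-2 with Col-0 and with their single mutants do so in part. The comparison of ski2-2 dcl4-2 dcl2-1 with ski2-2 dcl4-2 does so too. Clock genes rose in 7 and fell in 2 of 14 members in ein5-1 dcl4-2 against ein5-1, and rose in 6 and fell in 2 in ski2-2 dcl4-2 against ski2-2.

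**Figure D2:**
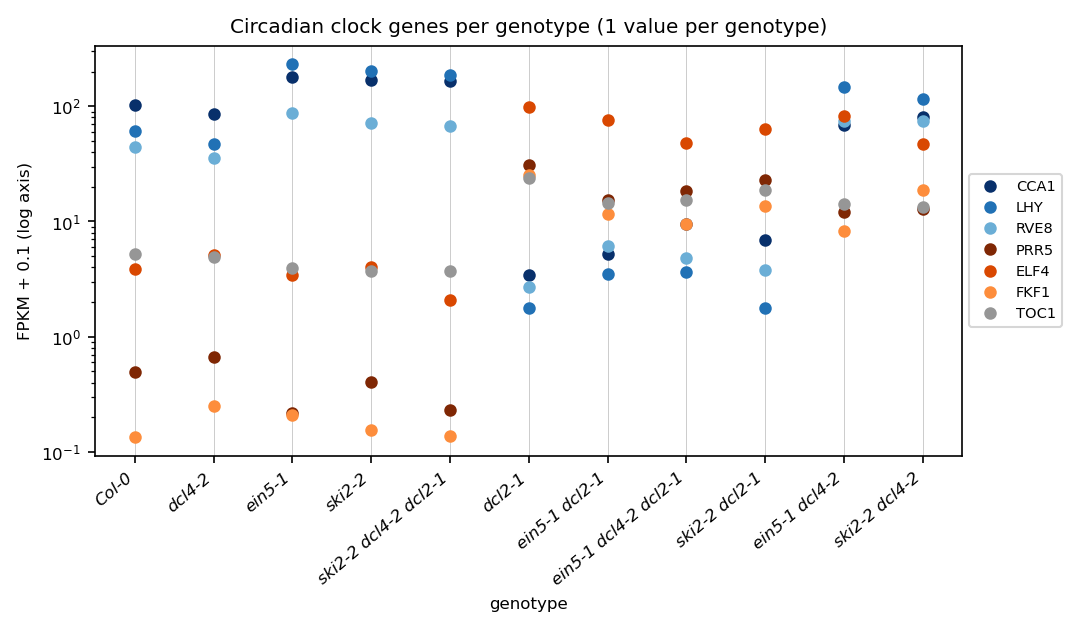
FPKM + 0.1 (log axis, 1 pooled value per genotype, no error) of 7 circadian clock genes in the 11 genotypes. CCA1, LHY and RVE8 were low and PRR5, ELF4 and FKF1 high in dcl2-1, ski2-2 dcl2-1, the triple ein5-1 dcl4-2 dcl2-1 and ein5-1 dcl2-1.

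The comparison of ein5-1 dcl4-2 with Col-0 asked what losing both EIN5 and DCL4 does to the transcriptome. Most genes of the heat shock, ABA, salicylic acid, jasmonate, senescence and anthocyanin lists rose, and most photosynthesis and cell division genes fell. Small heat shock proteins, which are chaperones, rose most: HSP17.4 (AT3G46230) was at 1646 FPKM against 1.85 FPKM in Col-0, and HSP17.6A (AT5G12030) at 1179 against 1.79 FPKM. HSP17.6C (AT1G53540) reached 827 FPKM from 0.353 FPKM, HSP17.6II (AT5G12020) 698 from 0.650 FPKM and HSP22 (AT4G10250) 456 from 0.200 FPKM. The falls were led by FBA5 (AT4G26530), a fructose-bisphosphate aldolase, at 13.4 against 790 FPKM, and LHCB2.3 (AT3G27690), a light-harvesting protein, at 80.6 against 3600.4 FPKM. Next came CA1 (AT3G01500), a carbonic anhydrase, at 109 against 4677 FPKM, AT3G16670 at 8.16 against 380 FPKM and AT2G39850 at 0.531 against 56.9 FPKM. By the q of the authors' deposited table, 3972 genes rose and 3176 fell, 1094 and 361 of them at least 8-fold. The q in the authors' deposited table was 0.0397 for HSP17.6C and 0.0396 for HSP22, close to the threshold of 0.05. Both had very low Col-0 values, and what set these q values was not tested. The median gene was shifted by 0.11 (log2) from Col-0 in this genotype. After quantile normalization, with the authors' q kept, 3298 genes were higher and 3837 lower. This moved the share of higher genes from 55.6% to 46.2%.

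Abscisic acid (ABA) and drought genes rose in 27 of 33 members and fell in none, by the authors' deposited table, with a median of 3.17. LEA4-5, a late embryogenesis abundant protein, went from 0.746 to 172 FPKM, the phosphatase gene HAI1 from 1.85 to 150 FPKM, KIN1 from 2.84 to 174 FPKM and RD29B from 0.158 to 50.7 FPKM. In the heat shock list 13 of 14 rose, and 14 did when adjusted over the list alone, with a median of 5.65. The member outside the call was HSP23.6, at 108 against 0.155 FPKM. Genes of the small heat shock family resemble each other, and reads may be split between copies. Anthocyanin and flavonoid genes rose in 14 of 15 members with a median of 3.77: UF3GT went from 23.4 to 565 FPKM, UGT75C1 from 29.4 to 687 FPKM, the MYB regulator PAP2 from 4.55 to 111 FPKM and TT19 from 64.1 to 1239.8 FPKM. FLS1, which leads to flavonols, fell from 87.2 to 37.0 FPKM.

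Immune genes of the salicylic acid list rose in 18 of 21 members with a median of 2.34. PR1 was at 1658 against 14.1 FPKM, the camalexin gene PAD3 at 118 against 2.54 FPKM, WRKY38 at 35.6 against 0.568 FPKM and FMO1 at 22.3 against 0.375 FPKM. Jasmonate genes rose in 13 of 17 members, with the storage proteins VSP2 at 606 against 40.3 FPKM and VSP1 at 481 against 55.5 FPKM and AOC2 at 665 against 74.1 FPKM, while the defensin PDF1.2 fell from 103 to 8.36 FPKM. Senescence genes rose in 12 of 13 members. The sugar transporter gene SWEET15 went from 2.63 to 404 FPKM, SAG21 from 36.5 to 2378 FPKM, SAG13 from 29.9 to 866 FPKM and the NAC factor ORE1 from 2.95 to 33.2 FPKM. In the ethylene list 4 of 17 rose and 1 fell: ACS2, ACS6, ACO4 and HCHIB rose, ACS2 from 0.188 to 12.8 FPKM, and ACO1 fell from 6.23 to 1.29 FPKM. Nitrogen genes rose in 11 of 23 members, 12 when adjusted over the list alone, with ASN2 at 468 against 26.2 FPKM, NIR1 (nitrite reductase) at 920 against 55.7 FPKM, NRT3.1 at 64.3 against 6.27 FPKM and UPM1 at 167 against 23.0 FPKM, and GLN2 and GLU1 fell.

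All 28 nuclear photosynthesis genes fell, with a median of -3.07. RBCS2B was at 448 against 7939 FPKM, RBCS3B at 920 against 16023 FPKM, RBCS1B at 410 against 6255 FPKM and LHCB2.2 at 480 against 5815 FPKM, and each RBCS gene shares sequence with its copies. Cell division genes fell in 15 of 18 members with a median of -1.33, such as the cyclin CYCB1;2 from 11.1 to 1.61 FPKM, CDKB2;1 from 17.5 to 3.39 FPKM, PCNA1 from 25.8 to 5.84 FPKM and KNOLLE from 28.4 to 6.79 FPKM. Among RNA silencing factors AGO2 rose from 5.16 to 19.3 FPKM and AGO3 from 0.386 to 2.89 FPKM, and AGO4, AGO10, DCL3 and RDR6 fell, AGO4 from 18.7 to 5.59 FPKM, of 19 measured. Of 23 RNA decay factors SOV alone rose, from 9.19 to 19.4 FPKM, and none fell. The miRNA target list had 6 rises and 7 falls among 41 members, with NAC1 at 28.5 against 6.45 FPKM and the growth regulators TCP4 at 10.6 against 38.8 FPKM, SPL9 at 1.82 against 8.06 FPKM and SPL15 at 0.290 against 3.22 FPKM. In the tasiRNA list TAS4, ARF4, HTT2, PAP1 and PAP2 rose, TAS4 from a listed 0 to 56.1 FPKM, and 12 of 17 members did not pass the test. Ribosomal protein genes rose in 1 and fell in 2 of 26 members. Clock genes rose in 6 of 14 and fell in 1, with ELF4 at 81.6 against 3.77 FPKM, LUX at 26.3 against 3.48 FPKM and LNK2 at 74.6 against 257 FPKM. The floral genes AP3, SEP1, SEP2 and FUL fell, SEP1 from 6.11 to 0.228 FPKM, of 10 measured, and of the root list PYK10 alone rose, from 38.8 to 254 FPKM.

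Each list median above is descriptive and was set against 10000 random lists of like expression. The ABA, heat shock, anthocyanin, salicylic acid, jasmonate, senescence and nitrogen medians lay above all of them to the percentile of 100, and photosynthesis and cell division lay at the percentile of 0. Tested against ein5-1, the double had 3168 rises and 2792 falls in the authors' deposited table, and against dcl4-2 it had 3855 rises and 3069 falls. After quantile normalization both splits turned, to 2768 higher and 3339 lower against ein5-1 and to 3176 higher and 3837 lower against dcl4-2, where the share of higher genes went from 55.7% to 45.3%. Photosynthesis genes fell in 28 of 28 members in both, and ABA genes rose in 23 of 33 against ein5-1 and 26 of 33 against dcl4-2. Against ein5-1 the largest rises were again HSP17.6C, HSP17.4 and HSP22, and the largest falls were AT2G47880 from 370 to 4.82 FPKM, MEE3 from 217 to 3.49 FPKM and AT3G62960 from 82.9 to 1.12 FPKM. Against dcl4-2 HSP17.6A, the sulfur response gene LSU1 (906 from 1.93 FPKM) and AT3G02480 (779 from 1.87 FPKM) led the rises, and FBA5, AT2G39850 and LHCB2.3 the falls.

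The comparison of ski2-2 dcl4-2 with Col-0 asked the same for SKI2 and DCL4. Most ABA and drought genes and most anthocyanin genes rose, all 28 photosynthesis genes and 10 of 18 cell division genes fell, and the heat shock list had a smaller median than in ein5-1 dcl4-2. LEA7 (AT1G52690), a late embryogenesis abundant protein, rose most, at 518 against 0.181 FPKM, with a q of 0.0253 in the authors' deposited table. LTP4 (AT5G59310), a lipid transfer protein, was at 1376 against 2.91 FPKM, AT2G05510 at 520 against 1.197 FPKM, the non-coding RNA AT1G67105 at 332 against 1.18 FPKM and AT4G08570 at 208 against 0.502 FPKM. MEE3 (AT2G21650) fell from 163 to 0.675 FPKM, AT3G16670 from 380 to 4.399 FPKM and XTH6 (AT5G65730), a cell wall enzyme, from 284 to 7.10 FPKM. NEET (AT5G51720) fell from 803 to 25.5 FPKM and FBA5 from 790 to 25.2 FPKM. In all, 2983 genes rose and 2712 fell by the q of the authors' deposited table, 838 and 250 of them at least 8-fold. The split turned to 2741 higher and 2888 lower after quantile normalization and to 1981 and 2218 at a minimum of 5 FPKM.

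Of 33 ABA and drought genes 30 rose in ski2-2 dcl4-2 and none fell, by the authors' deposited table, with a median of 2.33. RD29B was at 154 against 0.158 FPKM, LEA4-5 at 220 against 0.746 FPKM, KIN1 at 236 against 2.84 FPKM and HAI2 at 81.1 against 0.509 FPKM. Anthocyanin genes rose in 13 of 15 members with a median of 3.48, with PAP2 at 85.1 against 4.55 FPKM, UGT75C1 at 426 against 29.4 FPKM, F3'H at 392 against 27.0 FPKM and TT8 at 54.8 against 3.44 FPKM. In the heat shock list 7 of 14 rose, 9 when adjusted over the list alone, such as HSP70-4 from 12.3 to 317 FPKM, HSP90.1 from 5.62 to 33.8 FPKM and HSFA2 from 0.847 to 6.64 FPKM, and HSP21 was at 3.94 FPKM against a listed 0. Against ski2-2 the list had 4 rises and 1 fall with a median of -0.02, and HSP90.1 and HSFA2 were higher in ski2-2 (44.0 and 8.65 FPKM) than in the double. Salicylic acid genes rose in 11 of 21 members, with PR1 at 156 against 14.1 FPKM and FMO1 at 7.21 against 0.375 FPKM, and WRKY70 and WRKY54 fell. Jasmonate genes went both ways, with VSP2, AOC2, JAZ1 and THI2.1 up and VSP1, PDF1.2b, TAT3 and CLH1 down, and the list's median of -0.09 became 0.25 under quantile normalization. Senescence genes also went both ways, since SWEET15 (183 against 2.63 FPKM), SAG21 and WRKY6 rose and NAP and SEN1 fell. Nitrogen genes rose in 8 of 23 members, with NRT3.1 at 63.7 against 6.27 FPKM, ASN2 at 134 against 26.2 FPKM and NIR1 at 219 against 55.7 FPKM, and GLN2 and GLU1 fell. In the ethylene list EBF1, ACS2 and HCHIB rose, and falls included EIL1 and ACO1.

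All 28 photosynthesis genes fell in ski2-2 dcl4-2, with a median of -2.30, RBCS2B to 442, RBCS3B to 905, RBCS1B to 433 and PSAF, a photosystem subunit, from 6450.2 to 706 FPKM. Cell division genes fell in 10 of 18 members with a median of -0.95, PCNA1 to 6.76 FPKM and AUR1 from 7.88 to 1.79 FPKM among them. The tasiRNA list had 7 rises in 17 members, TAS4 at 41.1 FPKM against a listed 0, PAP2, PAP1 at 224 against 18.9 FPKM and HTT2 at 49.2 against 9.19 FPKM, and TAS3 fell from 40.7 to 8.95 FPKM. Of 41 miRNA targets 5 rose, NFYA5 from 4.02 to 27.3 FPKM, NFYA8, NAC1, TOE2 and APS4, and 8 fell, the superoxide dismutase gene CSD2 from 1080.03 to 287 FPKM and TCP4 from 38.8 to 13.9 FPKM. AGO2 rose from 5.16 to 11.9 FPKM as the sole change among 19 silencing factors, and none of 23 decay factors passed the test. RPS9C rose and RPL24A fell among 26 ribosomal protein genes, whose median of -0.40 became 0.05 under quantile normalization. Clock genes rose in 6 of 14 members and LNK2 fell, with ELF4 at 47.4 against 3.77 FPKM. AP3, PI and SEP1 of the floral list fell, SEP1 from 6.11 to 0.318 FPKM. PYK10, a root-abundant glucosidase, rose from 38.8 to 673 FPKM, and of a second root list of 12 genes, added before the tested values were seen, PER45, TIP2;3, HKT1, RCI3 and SKOR rose. The root iron transporter IRT1 stood at 60.6 FPKM against 0.253 FPKM in Col-0, without passing the test (q of 0.227 in the authors' deposited table), and it passed against ski2-2, where it was listed at 0.

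Against ski2-2 the double had 2789 rises and 2659 falls in the authors' deposited table, and against dcl4-2 it had 2902 rises and 2596 falls. After quantile normalization these were 2653 higher and 2765 lower, and 2621 higher and 2866 lower, so both splits turned. AT2G05510, LEA7 and LTP4 led the rises against ski2-2, and MEE3 (0.675 from 273 FPKM), AT1G67865 (40.1 from 3334 FPKM) and XTH6 the falls. Against dcl4-2 LTP4, LEA4-5 and AT4G08570 led the rises and MEE3, AT3G16670 and XTH6 the falls. Photosynthesis genes fell in 25 of 28 members against ski2-2 and in 28 of 28 against dcl4-2, and ABA genes rose in 24 and 26 of 33.

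Both doubles were then set side by side. Among 19007 genes considered in both comparisons with Col-0, 1981 rose in both and 1906 fell in both, against 506 and 453 from independent lists of the same lengths. In opposite directions went 57 and 10 genes. After quantile normalization 1755 were shared as higher and 2115 as lower. These comparisons share the Col-0 libraries, and part of the excess may come from them. The comparisons of ein5-1 dcl4-2 with ein5-1 and of ski2-2 dcl4-2 with ski2-2 share none, and gave 1529 shared rises and 1579 shared falls against 368 and 385, though both carry the clock difference described above. The controls ein5-1 and ski2-2 also resembled each other. With each gene centred on its mean over genotypes, they correlated at 0.68, against 0.12 and 0.22 with Col-0. A state common to these controls may therefore add to this overlap as well. The correlation of log2 differences across genes, which are not independent replicates, was 0.77 (covariance 1.14) with Col-0 and 0.69 (covariance 0.907) with the separate controls.

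The direct difference between ein5-1 dcl4-2 and ski2-2 dcl4-2 had no test in the table. By size, 2566 genes were at least 2-fold higher and 1362 at least 2-fold lower in ein5-1 dcl4-2. After quantile normalization the split was 2152 and 1743, a share of 55.3% in place of 65.3%. Heat shock genes were at least 2-fold higher in 12 of 14 members, salicylic acid genes in 17 of 21, jasmonate genes in 15 of 17 and senescence genes in 12 of 13, while of 15 anthocyanin genes 1 was 2-fold higher and 1 lower, and of 33 ABA genes 8 were higher and 5 lower, with a list median of -0.24. HSP17.6A stood at 1179 against 1.25 FPKM, HSP17.6II at 698 against 0.354 FPKM and HSP17.6C at 827 against 1.95 FPKM. IRT1 was at 1.09 against 60.6 FPKM, CYP82C4, an enzyme of iron mobilisation, at 0.0822 against 29.6 FPKM and AT3G12900 at 0.0370 against 20.4 FPKM.

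**Figure D3:**
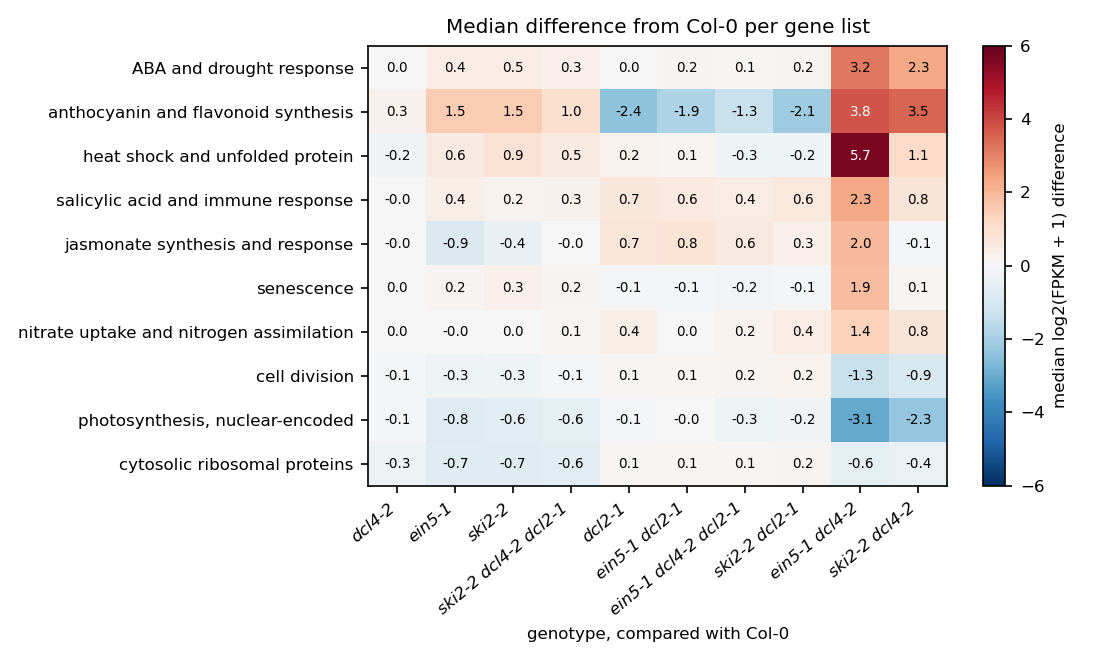
Median log2(FPKM + 1) difference from Col-0 (colour and number) of 10 gene lists (rows) in the 10 mutant genotypes (columns), from 1 pooled value per genotype, without error or test. The heat shock median was 5.65 in ein5-1 dcl4-2 and 1.15 in ski2-2 dcl4-2, and the photosynthesis medians there were -3.07 and -2.30.

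Adding dcl2-1 to ein5-1 dcl4-2 asked which changes need DCL2. Most genes of the heat shock, ABA, salicylic acid, jasmonate, senescence and anthocyanin lists fell, and all 28 photosynthesis genes rose. Genes listed at 0 in either genotype, such as HSP17.6C and HSP22 in the triple, were left out of the ranking that follows. The largest falls in it were HSP17.6II from 698 to 0.630 FPKM, LTP4 from 912 to 2.29 FPKM and the light stress gene ELIP1 (AT3G22840) from 1808 to 5.79 FPKM. SWEET15 (AT5G13170) followed, from 404 to 0.618 FPKM, and AT3G02480, from 779 to 2.96 FPKM. The largest rises were the expansin EXPA8 (AT2G40610) from 2.64 to 128 FPKM, AT1G13650 from 1.23 to 65.9 FPKM, FBA5 from 13.4 to 414 FPKM, LHCB2.3 from 80.6 to 2213 FPKM and PORB (AT4G27440), an enzyme of chlorophyll synthesis, from 45.8 to 1178 FPKM. There were 3202 rises and 3729 falls by the q of the authors' deposited table. After quantile normalization 3804 genes were higher and 3222 lower, so which direction held more genes depended on the scaling. In the same comparison CCA1 fell from 69.3 to 9.34 FPKM and LHY from 148 to 3.57 FPKM, so the clock state differed too.

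In the triple ein5-1 dcl4-2 dcl2-1 all 15 anthocyanin genes fell relative to the double, by the authors' deposited table, with a median of -5.05, F3H from 1239 to 15.6 FPKM and PAP2 from 111 to 0.350 FPKM. Heat shock genes fell in 13 of 14 members with a median of -6.39, HSP17.6C, HSP22 and HSP21 from 827, 456 and 169 FPKM to a listed 0, and HSP17.4 was listed at 0 against 1646 FPKM without passing the test. ABA genes fell in 23 of 33 members, such as LEA4-5 from 172 to 0.782 FPKM, HAI1 from 150 to 0.964 FPKM and RD20 from 1055 to 26.7 FPKM, and COR15B rose from 73.9 to 275 FPKM. Salicylic acid genes fell in 16 of 21 (FMO1 from 22.3 to 0.106 FPKM), jasmonate genes in 12 of 17 (TAT3 from 265 to 39.3 FPKM) with PDF1.2 up to 152 FPKM, senescence genes in 12 of 13 (SAG21 from 2378 to 51.3 FPKM) and nitrogen genes in 11 of 23 (ASN2 from 468 to 43.5 FPKM). Photosynthesis genes rose in 28 of 28 members with a median of 2.90, LHCA1 from 799 to 7940.4 FPKM and LHCB5 from 882 to 8674 FPKM, and cell division genes in 15 of 18, CYCB1;2 from 1.61 to 13.9 FPKM. AGO2 and AGO3 fell and AGO4, DCL3 and HYL1 rose. In the tasiRNA list TAS4, HTT1, PAP1 and PAP2 fell and TAS1C and ARF3 rose. The miRNA target list had 9 rises and 9 falls (10 falls when adjusted over the list alone), SPL9 from 1.82 to 12.1 FPKM and NFYA2 from 17.9 to 3.06 FPKM among them. In the ethylene list ACS2, ACS6, ACO4 and HCHIB fell and ACO1 rose. RPL10B, RPL24A, RPL28A and RPS6A rose and RPS9C fell among 26 ribosomal protein genes, no decay factor passed the test, AG and FUL of the floral list rose, and PYK10 fell to 73.2 FPKM.

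Adding dcl2-1 to ski2-2 dcl4-2 asked the same in the other background. The clock state differed here too, with CCA1 up from 80.0 to 165 FPKM and PRR5 down from 12.7 to 0.133 FPKM. The median of evening output genes less that of dawn output genes, set against Col-0, was 3.61 in the double and -0.31 in the triple. MEE3 rose from 0.675 to 170 FPKM, AT1G67865 from 40.1 to 2981 FPKM, XTH6 from 7.10 to 417 FPKM, AT1G66100 from 15.8 to 554 FPKM and AT2G20870 from 0.512 to 48.1 FPKM. LEA7 fell from 518 to 0.380 FPKM, LTP4 from 1376 to 3.17 FPKM, MLP34 (AT1G70850) from 255 to 0.467 FPKM, the glycine-rich protein GRP9 (AT2G05440) from 1183 to 6.17 FPKM and RD29B (AT5G52300) from 154 to 0.218 FPKM. There were 2700 rises and 2813 falls by the q of the authors' deposited table, and this split turned to 2844 higher and 2665 lower after quantile normalization and to 2196 and 1795 at a minimum of 5 FPKM. ABA genes fell in 26 of 33 members with a median of -1.83, P5CS1, which makes proline, from 811 to 13.7 FPKM and LEA4-5 from 220 to 2.83 FPKM. Anthocyanin genes fell in 13 of 15 with a median of -2.48, TT8 from 54.8 to 7.77 FPKM and UF3GT from 275 to 45.2 FPKM. Photosynthesis genes rose in 25 of 28 with a median of 1.68, RBCS2B from 442 to 5419.98 FPKM and LHCB2.1 from 932 to 4881 FPKM, and cell division genes in 9 of 18, PCNA1 from 6.76 to 22.5 FPKM.

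In the same comparison HSP70-4, HSFA7A, HSP21 and HSP22 fell among 14 heat shock genes, HSP70-4 from 317 to 115 FPKM. In the salicylic acid list PR2, PR5, FMO1, CBP60g and PAD3 fell and WRKY70 and WRKY54 rose. Among senescence genes SWEET15 (183 to 4.89 FPKM), SAG21, WRKY6 and SEN1 fell and NAP and WRKY53 rose. Nitrogen genes fell in 9 of 23 members, the nitrate transporter NRT2.1 from 48.6 to 0.440 FPKM and ASN1 from 22.0 to 1.08 FPKM, and NIA2, NRT1.1, GLN2 and GLU1 rose. TAS4, PAP1 and PAP2 fell and TAS1C and TAS3 rose, TAS3 from 8.95 to 77.1 FPKM. Of 41 miRNA targets 7 rose, CSD2 from 287 to 929 FPKM and SPL15 from 1.05 to 5.02 FPKM among them, and NAC1, TOE2, NFYA2, NFYA5 and NFYA8 fell. AOC2 and JAZ1 of the jasmonate list fell and VSP1, PDF1.2b and CLH1 rose. In the ethylene list HCHIB fell, and rises included ACO1. RDR2 of the silencing factors fell, RPS9C alone of the ribosomal protein genes fell, and no decay factor passed the test. Clock genes fell in 7 of 14 members, ELF4 from 47.4 to 1.98 FPKM among them, and CCA1 and LNK2 rose. The floral genes AP3, PI, SEP1, FUL and FT rose, SEP1 from 0.318 to 4.50 FPKM. The root genes PYK10, WOX5, EXPA7 and EXPA18 fell, PYK10 from 673 to 31.4 FPKM.

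Of the 3972 genes that rose in ein5-1 dcl4-2 over Col-0, 402 (10.1%) were also at least 2-fold higher than Col-0 in the triple with dcl2-1, by size, and 199 of the 3176 that fell were 2-fold lower there. For ski2-2 dcl4-2, 216 of 2983 and 197 of 2712 were so in its triple. Of the 3972 genes, 10.9% were also 2-fold higher in dcl2-1, 11.1% in ein5-1 and 1.26% in dcl4-2. In ski2-2 alone 219 of the 2983 were so. The size scale is stricter, since 89.0% of the 3972 passed it in ein5-1 dcl4-2 itself. Among all 20704 genes at 1 FPKM, 873 were 2-fold higher than Col-0 in the ein5-1 triple. These shares therefore do not measure the part that needs no DCL2. The changes with dcl2-1 overlapped between backgrounds without a shared library, with 1392 shared rises and 1271 shared falls among 18850 genes, against 440 and 447 from independent lists. Genes that rose on adding dcl4-2 to ein5-1 also fell on adding dcl2-1 to ski2-2 dcl4-2 in 1475 cases against 370, and those that fell also rose there in 1576 cases against 389. In reverse, 1244 genes that rose on adding dcl4-2 to ski2-2 fell on adding dcl2-1 to ein5-1 dcl4-2, against 446, and 1328 went the other way, against 432. Evening less dawn output, against Col-0, was 0.10 in ein5-1 and 2.43 in ein5-1 dcl4-2. It was 3.61 in ski2-2 dcl4-2 and -0.31 in its triple. The clock shift thus reversed in the first pair too, and ein5-1 correlated with that triple at 0.59 across gene-centred values. That excess cannot be assigned to the mutations alone. In the reverse pair ski2-2 was at -0.22 and the ein5-1 triple at 3.19, so the shift did not reverse on this index. The evening median alone did go down, from 2.06 in ein5-1 dcl4-2 to 1.61 in the ein5-1 triple. The dawn median went from -0.37 to -1.57. A part of the clock difference in the reverse overlap is therefore not excluded.

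Single mutants and combinations with dcl2-1 had no test against Col-0 and are given by size. At least 2-fold higher and lower than Col-0 were 192 and 86 genes in dcl4-2, 945 and 773 in dcl2-1, 739 and 634 in ein5-1 and 534 and 491 in ski2-2. The numbers were 1048 and 908 in ein5-1 dcl2-1, 873 and 657 in ein5-1 dcl4-2 dcl2-1, 929 and 752 in ski2-2 dcl2-1 and 524 and 488 in ski2-2 dcl4-2 dcl2-1. After quantile normalization the splits of ein5-1 (647 and 661), ski2-2 (492 and 499) and ein5-1 dcl2-1 (936 and 964) turned to slightly more lower than higher genes. Before it, on the same scale, ein5-1 dcl4-2 had 3926 and 2794 and ski2-2 dcl4-2 had 2751 and 2483. Anthocyanin genes were at least 2-fold higher in 14 of 15 members in ein5-1, 13 in ski2-2 and 7 in ski2-2 dcl4-2 dcl2-1, and at least 2-fold lower in 14 in dcl2-1, 13 in ein5-1 dcl2-1, 11 in ein5-1 dcl4-2 dcl2-1 and 14 in ski2-2 dcl2-1, the genotypes with low CCA1. Photosynthesis genes were 2-fold lower in 10 of 28 members in ein5-1, 5 in dcl2-1, 4 each in ski2-2, ein5-1 dcl4-2 dcl2-1 and ski2-2 dcl2-1, 3 in ein5-1 dcl2-1, 2 in ski2-2 dcl4-2 dcl2-1 and 0 in dcl4-2. The 5 in dcl2-1 include LHCB1.3, whose listed 0 there may be a failed estimate. Jasmonate genes were 2-fold lower in 7 of 17 members in ein5-1, 5 in ski2-2 and 1 in ski2-2 dcl4-2 dcl2-1, and 2-fold higher in 5 each in dcl2-1, ein5-1 dcl2-1 and ski2-2 dcl2-1, 3 in ein5-1 dcl4-2 dcl2-1 and 2 in ski2-2 dcl4-2 dcl2-1. Ribosomal protein genes had a median of -0.72 in both ein5-1 and ski2-2, -0.61 in ski2-2 dcl4-2 dcl2-1, -0.30 in dcl4-2 and 0.08 to 0.18 in the other 4. Across gene-centred values ein5-1, ski2-2 and ski2-2 dcl4-2 dcl2-1 correlated at 0.59 to 0.68, though that triple lacks ein5-1. Those other 4 genotypes correlated at 0.52 to 0.61 with each other, and Col-0 with dcl4-2 at 0.52. What sets these groups apart was not tested, so differences from Col-0 cannot be assigned to single mutations.

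By the same naming rule, AT1G67105 (70.1 against 1.18 FPKM), AT3G01345 and AT2G15555 were farthest above Col-0 in dcl4-2, and AT2G01008 (2.41 against 50.7 FPKM), AT3G41762 and AT5G09672 farthest below. In dcl2-1, AT2G33830 (549 against 5.24 FPKM), AT1G07050 and AT1G56300 were highest over Col-0. Lowest among genes above 0 in both were ELIP2 (0.617 against 65.4 FPKM), ELIP1 (3.18 against 153 FPKM) and AT2G01008. LHCB1.3, listed at 0 in dcl2-1, was left out by this rule. AT2G33830, AT1G56300 and AT5G62360 were highest over Col-0 in ski2-2 dcl2-1, the triple ein5-1 dcl4-2 dcl2-1 and ein5-1 dcl2-1, where ELIP2, ELIP1 and either AT2G01008 or LHY were lowest. In ein5-1, AT5G52740 (27.1 against 0.946 FPKM), AT5G03285 and AT3G62960 stood highest, and PDF1.2 (3.69 against 103 FPKM), GASA6 (6.99 against 153 FPKM) and PORB (14.4 against 295 FPKM) lowest. In ski2-2, AT5G52740, AT5G24240 and GolS2, which makes galactinol (50.04 against 3.68 FPKM), stood highest, and AT2G01008, AT3G41762 and PORB (17.7 FPKM) lowest. In ski2-2 dcl4-2 dcl2-1, AT1G27565, AT1G53542 and AT5G52740 stood highest and AT2G01008, AT3G41762 and PORB (15.9 FPKM) lowest.

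The siRNA source genes NIA1, NIA2, SMXL4 and SMXL5 were taken from what is known of the study, so their direction is not independent evidence. NIA1 (AT1G77760), a nitrate reductase, was at 113 FPKM in ein5-1 dcl4-2 against 20.9 FPKM in Col-0, with a log2 of 2.43 in the authors' deposited table. It was at 39.6 FPKM in ski2-2 dcl4-2, 1.90-fold above Col-0 and short of the 2-fold threshold, and fell to 18.8 FPKM in ein5-1 dcl4-2 dcl2-1. In the other genotypes NIA1 was at 21.02 (dcl4-2), 11.1 (dcl2-1), 21.4 (ein5-1), 16.3 (ein5-1 dcl2-1), 31.7 (ski2-2), 14.6 (ski2-2 dcl2-1) and 32.1 FPKM (ski2-2 dcl4-2 dcl2-1). NIA1 thus split with the clock state, at 11.1 to 18.8 FPKM in the 4 genotypes with low CCA1, the ein5-1 triple among them. It was at 20.9 to 32.1 FPKM in the 5 with CCA1 at 85.5 to 180 FPKM. The 113 FPKM of ein5-1 dcl4-2 lay above both ranges. Its fall to 18.8 FPKM still cannot be assigned to dcl2-1 alone, and the part that goes with clock state was not tested. NIA2 (AT1G37130) was at 109 FPKM in Col-0, 399 in ein5-1, 489 in ski2-2 and 531 in ski2-2 dcl4-2 dcl2-1. In ein5-1 dcl4-2 it was at 172 FPKM, below ein5-1 by a log2 of -1.21 in the authors' deposited table. In ski2-2 dcl4-2 it was at 83.6 FPKM, below ski2-2 by a log2 of -2.55 and below the triple, which was higher by 2.67, both in the authors' deposited table. NIA2 was at 84.5 (dcl4-2), 98.0 (dcl2-1), 145 (ein5-1 dcl2-1), 140 (ein5-1 dcl4-2 dcl2-1) and 150 FPKM (ski2-2 dcl2-1).

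SMXL4 (AT4G29920) fell in ein5-1 dcl4-2 from 2.05 to 0.565 FPKM and rose to 1.69 FPKM in the triple. It was at 1.61 FPKM in ski2-2 dcl4-2 with a q of 0.202 in the authors' deposited table, and between 1.296 and 2.68 FPKM in every other genotype but ein5-1 dcl4-2. SMXL5 (AT5G57130) was at 4.81 FPKM in Col-0, 2.63 in ein5-1 dcl4-2, 8.57 in ski2-2 dcl4-2, 6.34 in ein5-1 and 7.11 in ski2-2. It fell in ein5-1 dcl4-2 relative to ein5-1 and rose in ski2-2 dcl4-2 relative to dcl4-2, and was less than 2-fold from Col-0 in both doubles. SMXL5 was at 4.199 (dcl4-2), 5.13 (dcl2-1), 4.66 (ein5-1 dcl2-1), 4.41 (ein5-1 dcl4-2 dcl2-1), 4.48 (ski2-2 dcl2-1) and 6.94 FPKM (ski2-2 dcl4-2 dcl2-1).

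Whether the doubles departed from the sum of their single mutants was read by size on the log2 scale, with no test. For ein5-1 and dcl4-2, 3225 genes lay at least 2-fold above and 2476 below the sum, and in 2620 and 1705 of these the double itself was 2-fold higher or lower than Col-0. For ski2-2 and dcl4-2, 2608 lay above and 2474 below, with 1837 and 1589 also 2-fold higher or lower than Col-0 in the double. After quantile normalization 2747 genes lay above and 3063 below for ein5-1 and dcl4-2, and 2460 above and 2787 below for ski2-2 and dcl4-2. Which side held more genes was therefore not settled for either pair. Evening less dawn output, against Col-0, was 0.02 in dcl4-2, 0.10 in ein5-1 and -0.22 in ski2-2. It was 2.43 in ein5-1 dcl4-2 and 3.61 in ski2-2 dcl4-2. These counts therefore include the clock difference of the doubles and cannot be assigned to the mutations alone.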

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

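Of 137 values of 20 counts under alternatives, 113 stayed within 1.5 times of the main count and 24 did not. For the 9 comparisons by size, dropping the FPKM minimum could not change the count. A log2(FPKM + 1) difference of 1 already needs 1 FPKM, so these matches among the 113 carry no information. Without a minimum log2, calls by the authors' q rose to 13294 for ein5-1 dcl4-2 vs Col-0, 12242 vs ein5-1, 13246 vs dcl4-2, 11912 for ski2-2 dcl4-2 vs Col-0, 11768 vs ski2-2 and 11807 vs dcl4-2. They rose to 13111 and 11914 on adding dcl2-1 to the ein5-1 and ski2-2 doubles, and to 8318 for the overlap of both doubles (main 3887; 3108 with controls that share no library). This follows from dropping the threshold. With a pseudocount of 0.1 the untested counts against Col-0 were 866 (dcl4-2), 2809 (dcl2-1), 2534 (ein5-1), 2033 (ski2-2), 3298 (ein5-1 dcl2-1), 2682 (ein5-1 dcl4-2 dcl2-1), 2813 (ski2-2 dcl2-1) and 2081 (ski2-2 dcl4-2 dcl2-1), since genes near 0 enter. At 5 FPKM dcl4-2 had 185. Leaving out 2642 genes 2-fold apart in dcl2-1 or ein5-1, an alternative chosen after the data were seen, gave 154 (dcl4-2), 177 (ski2-2), 694 (ein5-1 dcl2-1), 303 (ein5-1 dcl4-2 dcl2-1), 340 (ski2-2 dcl2-1) and 278 (ski2-2 dcl4-2 dcl2-1); the cause was not tested, and it could not be run for dcl2-1 and ein5-1. It left 5603 for ein5-1 dcl4-2 vs Col-0 and 4443 for ski2-2 dcl4-2 vs Col-0. Also chosen after were the controls without shared libraries, a pseudocount of 1 for tested comparisons, all alternatives of the comparisons with dcl4-2, and those of the overlap and the list medians other than median-of-ratios scaling and, for the overlap, no minimum log2. No named call of 730 reversed, 27 fell under a log2 of 1 in an alternative, and 14 list medians changed sign. A change of pseudocount cannot reverse a sign, and the median-of-ratios factors were only 0.977 to 1.06. With named genes picked for large or called changes, the lack of reversals under these settings was close to fixed in advance. No paired analysis was possible because the table holds 1 pooled value per genotype. For the same reason leave-one-out, a replicate block, a fit of only the compared libraries, eBayes without trend, camera and simulated shared controls were not run.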

Other observations

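Lists of nutrient limitation genes were chosen after the values were seen, and so were the tests of another genotype in a column, of nutrient limitation and of both readings of LHCB1.3. By the authors' deposited table sulfur limitation genes rose in 11 of 14 members in ein5-1 dcl4-2 over Col-0, LSU1 from 3.05 to 906 FPKM and SDI1 from 1.94 to 178 FPKM, and in 9 in ski2-2 dcl4-2. They fell in 11 and 8 (9 when adjusted over the list alone) on adding dcl2-1. Iron limitation genes rose in 9 of 11 and 8 of 11, IMA1 from 3.81 to 206 and 92.6 FPKM, and fell in 7 and 8 on adding dcl2-1. Phosphate limitation genes rose in 7 of 10 and 4 of 10, PAP17 from 7.22 to 201 and 56.3 FPKM, and fell in 4 and 5. No explanation of these was tested.

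Clock genes stood apart in dcl2-1, ski2-2 dcl2-1, the triple ein5-1 dcl4-2 dcl2-1 and ein5-1 dcl2-1 despite the same labelled hour. Collection at another time of day could give this, and evening minus dawn output genes were shifted by 3.19 to 5.66 (log2) in these 4, in separate lists. Loss of DCL2 as the whole cause is argued against by ski2-2 dcl4-2 dcl2-1, at -0.31. A genotype with intact DCL2 in that column is argued against by its DCL2 of 1.92 FPKM, below the lowest intact 4.89. One with intact DCL4 is argued against by its ARF4 of 51.8 FPKM, above the highest intact 14.6. These genes do not separate it from ein5-1 dcl4-2 dcl2-1, though EIN5 ranges with and without ein5-1 did not overlap. SKI2 did not separate ski2-2. The doubles ein5-1 dcl4-2 and ski2-2 dcl4-2 were also shifted, by 2.43 and 3.61, with CCA1 still high. Whether the hour, the sowing or biology differed stays open. Which group departs from its labelled hour is not settled either. Col-0, dcl4-2, ein5-1, ski2-2 and ski2-2 dcl4-2 dcl2-1 had the morning gene CCA1 at 85.5 to 180 FPKM. PRR5, expressed later in the day, was at 0.117 to 0.568 FPKM there. The departure may therefore lie with Col-0 and its group, which bears on every comparison with Col-0.

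Root genes were high in ski2-2 dcl4-2, with PYK10 at 673 FPKM and IRT1 at 60.6 FPKM. Root tissue in the harvest may explain it: a second root list had a median of 0.68, between the bounds written before, with 11 of 12 genes highest there. Its 8 genes that reached 1 FPKM in a genotype had a median of 1.69, a selection that the written bounds did not include. Nutrient limitation in the aerial part alone should leave root structure genes unmoved, and 6 of 6 were highest there, 4 above 1 FPKM. The low values leave both open. PYK10 also stood out in ein5-1 dcl4-2, at 254 FPKM against at most 73.2 FPKM in the remaining 9 genotypes. It was the only gene of the fixed root list that rose over Col-0 in ein5-1 dcl4-2. Of all genotypes ski2-2 dcl4-2 had the most genes at 1 FPKM (18976) and the fewest at 0 (9701). How far that bears on root genes near 0 was not tested.

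LHCB1.3 was listed at 0 in dcl2-1 and at 5011 to 40528 FPKM elsewhere. A failed estimate could do this, since LHCB1.1, a near-identical copy, kept a ratio to Col-0 of 0.68. A loss through dcl2-1 is argued against by the ratios of 0.505 to 1.23 in the 4 other genotypes with that allele. AT2G40205, listed at 0 in ein5-1 dcl4-2 alone and at 1288 to 10157 FPKM elsewhere, was not tested.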
